A study of Homo sapiens with 96 samples.

How the data were processed

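The data were single-cell and population RNA-seq of T47D cells. Per the labels' protocols, cells were kept for 3 days in medium free of phenol red with 5% charcoal-stripped serum, stained with a tracker dye 24 h before treatment (green for 0 and 3 h, orange for 6 and 12 h), treated with estradiol or ethanol, and dissociated to single cells. Poly-A RNA libraries were made with the Nextera XT kit, which does not keep the strand. The dose, and whether the 0 h cells received ethanol, are not given in the sources used here. MCF7 cells of the same study were not analysed here.

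The deposited table gives FPKM, a measure scaled for gene length and library size, for 57424 genes in 96 libraries, as computed by the authors. TopHat2 2.0.6 and the genome build hg19 are named in the submitters' processing notes. The quantifier and the annotation release are not given in the sources used here, and no coordinates are printed because the reference at hand is of another build. No counts were at hand, so no count-based test was used. The table's columns carry the sample titles, and each was matched to 1 sample. No column was left unused. A total of 273 symbols stand on more than 1 line of the table, 2312 lines in all, and genes were followed by their Ensembl identifier; a symbol on more than 1 line was not used in a list.

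Groups were the time points given by the labels, with cells and population libraries kept apart. Well names carry a prefix at 3 h and 6 h and none at 0 h and 12 h. What it marks is not stated, so it could not be adjusted for. Comparisons were 12, 3 and 6 h against 0 h, and 6 h against 3 h. The labels do not give the number of cultures. Because 1 per time point was assumed, cells were not treated as replicates, and no test was run.

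For each gene the mean FPKM over the cells of a time point was taken, and the log2 ratio of 2 means was computed with a pseudocount of 1 FPKM. It understates differences of low genes. The same ratio was computed from the 2 population libraries. Genes with a mean of at least 1 FPKM in either group counted as measured. A gene was called present in a cell at 1 FPKM or more, and shares of cells carry exact Clopper-Pearson 95% intervals. For a share of 0 the limit is 3 counts over the number of cells. Intervals and limits cover counting error only.

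Before the data were examined, 27 gene lists were fixed: estrogen targets, estrogen-repressed genes, mitochondrial folate, cytosolic folate, serine and glycine, purine, pyrimidine and deoxynucleotide, polyamine synthesis, polyamine catabolism and antizymes, ribosome biogenesis, G1/S, G2/M, cholesterol, glycolysis, nuclear oxidative phosphorylation, ATF4 and unfolded protein, immediate early and stress, NRF2 and thiol stress, interferon, housekeeping, luminal, basal and myoepithelial, fibroblast, immune, endothelial, mitochondrially encoded and ribosomal protein genes. Of 265 symbols asked for, 264 were found, and PECAM1 was not. Lists are described by the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. For the population libraries, measured genes and bins were those of the cells, so these random lists were not matched on expression in the population libraries. Only the alternative with population libraries in place of cells used their own filter and bins. The mitochondrially encoded list had 37 entries and the ribosomal protein list 84. Basal, myoepithelial and endothelial lists had too few measured members for a median.

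Named genes were fixed by rule before the data were examined: a mean of at least 5 FPKM and presence in at least 50% of the cells of the higher group, and a log2 ratio of at least 1 in size with the same sign in cells and population libraries, ranked by the smaller of the 2 sizes. The first 12 in each direction were named for 12 h against 0 h, and the first 6 for each other comparison. Genes without a symbol, mitochondrial pseudogenes and sex-linked marker genes were left out. List members given as examples were chosen after their values were seen, as were CYP1A1 and CYP1B1 where the rule did not name them.

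FPKM sums ran from 441414 to 1199750 per library. The steps between low values gave a relative depth for each library, if 1 step is 1 fragment: of 4560 library pairs 78.4% fitted within 0.1 log2 units, and relative depths of the cells ran from 0.606 to 1.32. Absolute depth is unknown. The highest correlation between any 2 libraries was 0.952 and 0 columns were identical.

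Data standing in for 12 h against 0 h, with 14503 genes, were simulated by drawing both groups from the 0 h cells. No 12 h cell entered, so a shift carried by those cells was not simulated. Planted folds of 2 and 4 added log2 ratios of 0.96 and 1.93, and planted folds of 0.5 and 0.25 added -0.89 and -1.70. Of 500 unchanged lists, 2.8% fell outside the central 95%. These lists were random genes, so this share does not cover lists whose members vary together between cells. The relative depth was tested on 24 simulated libraries, with errors of at most 0.011 log2 units. Their values were made from whole fragments, so that assumption itself was not tested.

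Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, the mean of log values, a mean without the highest and lowest 10% of cells, rescaling each library to the same sum, centering on the median of all genes, leaving out cells with few genes, population libraries in place of cells, a filter at 10 FPKM for the correlations, and presence at 0.1 and 5 FPKM. Leaving out cells with at least 50% of their sum in mitochondrial genes, leaving out those genes, both together, and leaving out the highest cell of each group were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.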

Results

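Gene expression was measured in single cells of T47D, an established breast cancer line that grows with estrogen and carries the estrogen receptor, over a time course of treatment with estradiol. The libraries comprised 92 cells, with 24 at 0 h, 20 at 3 h, 24 at 6 h and 24 at 12 h, and 4 population libraries made from many cells, 1 per time point. The labels do not give the number of cultures; 1 per time point was assumed, so no p-value or count of changed genes is given. Each SD below is the spread of the cells, and each population library is a second reading of its time point rather than a replicate. The purpose of the series, as its title states it, was to follow estrogen signaling into the mitochondrial folate pathway and the synthesis of purines and polyamines.

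The cells had 8095 ± 469 genes with at least 1 FPKM at 0 h (mean ± SD), 6988 ± 1553 at 3 h, 8374 ± 565 at 6 h and 7503 ± 1283 at 12 h, against 12582 to 13034 in the population libraries. Genes encoded in mitochondrial DNA took 25.9 ± 8.52% of the FPKM sum at 0 h, 42.8 ± 20.6% at 3 h, 24.3 ± 8.10% at 6 h and 34.9 ± 22% at 12 h. The population libraries had 9.22%, 17.8%, 17.3% and 9.18%. Of the sum at 6 h, 7.72% lay in 1 gene, MT-TL1. The median log2 ratio of the mitochondrially encoded genes against 0 h in the population libraries was -0.053 at 6 h and 0.90 at 3 h. Cells with at least 50% of the sum in these genes numbered 6 of 20 at 3 h (30%, exact 95% interval 11.9 to 54.3%) and 6 of 24 at 12 h (25%, 9.77 to 46.7%). At 0 h and at 6 h there were 0 of 24, which allows a share of up to 12.5%. These 12 cells had 3333 to 7220 genes with at least 1 FPKM, against 6745 to 9679 in the other 80. The intervals cover counting error only.

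**Figure D1:**
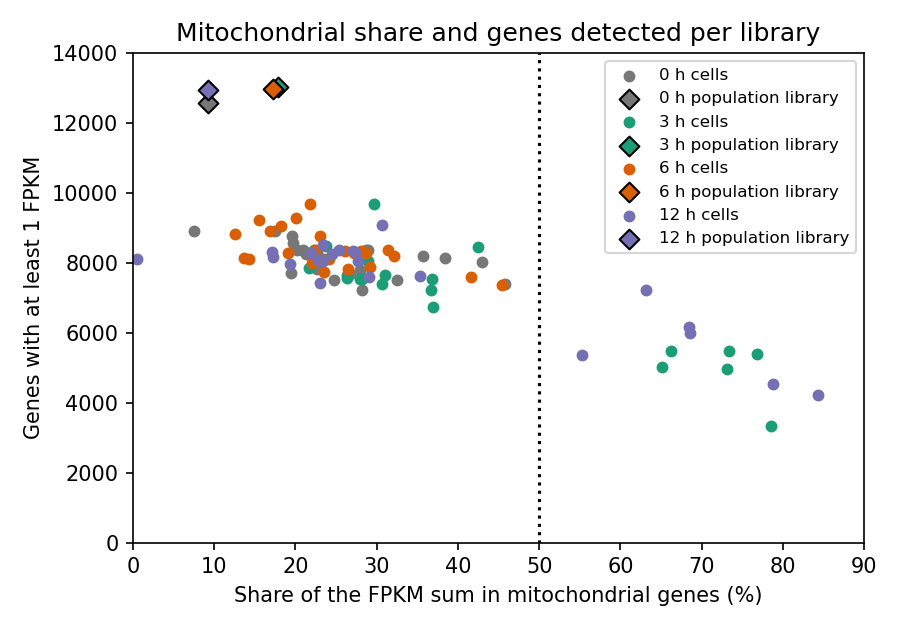
Each circle is 1 cell and each diamond 1 population library, colored by time, with the share of the FPKM sum in mitochondrial genes (%) on the x axis and the number of genes with at least 1 FPKM on the y axis. To the right of the dotted line at 50% lie 6 cells of 3 h and 6 cells of 12 h.

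The comparison of 12 h with 0 h asked what differed after the longest treatment. Known targets of the estrogen receptor were higher at 12 h: of 26 measured targets, 24 were higher and 2 lower in the cells, 20 were at least 1.5-fold higher, and 22 were higher in both the cells and the population libraries. GREB1, a cofactor of the receptor, averaged 20.9 ± 15 FPKM at 12 h and 6.48 ± 10.8 at 0 h (log2 ratio 1.55, population 1.27). PGR, the progesterone receptor, averaged 59.6 ± 50.8 against 28.6 ± 24.4 (1.03, population 0.81). SIAH2, a ubiquitin ligase, and FKBP4, a cochaperone of steroid receptors, had log2 ratios of 1.91 and 1.56. CXCL12, a secreted chemokine, reached 1 FPKM in 12 of 24 cells at 12 h (50%, 29.1 to 70.9%) and in 0 of 24 at 0 h, which allows up to 12.5%.

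The median log2 ratio of the estrogen targets was 1.09 in the cells and 0.57 in the population libraries. Both lay at percentile 100 of 10000 random lists matched on mean expression in the cells, as a description of these libraries. The central 95% of the random lists in the cells ran from -0.47 to 0.12. Without the cells with a high mitochondrial share the median was 1.21. Genes known to be repressed by estrogen went the other way, with 6 of 6 members measured in the cells lower in both kinds of library. Of these, 2 were at least 1.5-fold lower in both. BMF and PSCA, the members not measured in the cells, were higher in the population libraries at 0.47 and 0.64. The median of the 6 was -1.08 in the cells (percentile 0.08) and -0.43 in the population libraries (percentile 4.60). BLNK, a signaling adaptor, averaged 32.5 ± 38.5 FPKM against 86.9 ± 50.6, and the receptor kinase ERBB2 6.20 ± 7.40 against 17.4 ± 19.2. Single cells weighed on some targets. For MYC, a transcription factor that drives growth, 1 cell held 74.2% of the 0 h sum, and the log2 ratio was 1.14 with it and 2.13 without the highest cell of each group. PDZK1, a scaffold protein, was lower in the cells at -1.14 and higher in the population libraries at 0.27. The dye also differed between 12 h and 0 h.

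**Figure D2:**
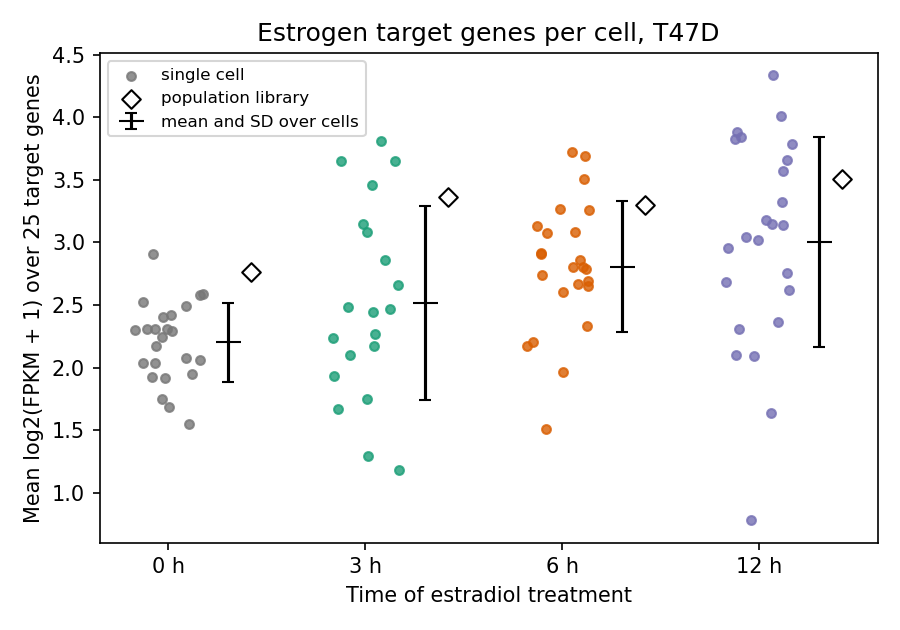
Each circle is 1 cell, placed by time on the x axis and by its mean log2(FPKM + 1) over 25 estrogen target genes on the y axis, with the mean and SD over cells as a bar and the population library as a diamond. Cells above the highest 0 h cell numbered 6 of 20 at 3 h, 9 of 24 at 6 h and 15 of 24 at 12 h.

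Per cell, the mean log2(FPKM + 1) over 25 estrogen targets was 2.20 ± 0.32 at 0 h, 2.52 ± 0.77 at 3 h, 2.81 ± 0.52 at 6 h and 3.00 ± 0.84 at 12 h. The share of cells above the highest 0 h cell was 30% at 3 h (11.9 to 54.3%), 37.5% at 6 h (18.8 to 59.4%) and 62.5% at 12 h (40.6 to 81.2%). Without the cells with a high mitochondrial share it was 2.86 ± 0.61 at 3 h, with 6 of 14 cells above the highest 0 h cell, and 3.30 ± 0.61 at 12 h, with 14 of 18. The 3 h mean then lay slightly above that of 6 h, so the order of 3 h and 6 h depends on those cells. The 12 h cells spanned 0.78 to 4.33, and the lowest of them had a high mitochondrial share.

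The mitochondrial folate enzymes, which move carbon units from serine to formate, had 4 of 5 measured members higher and 1 lower at 12 h in the cells. Their median log2 ratio of 0.54 (percentile 96.0) lay inside the random lists, which ran from -0.91 to 0.65, and the population median of the same 5 members was 0.15 (percentile 84.8). Over the 4 members measured in the population libraries themselves, the median of the mitochondrial folate list was -0.32, so the population libraries give no firm direction. SHMT2, which takes the carbon unit from serine, averaged 25 FPKM at 12 h and 21 at 0 h (log2 ratio 0.24, population 0.23). MTHFD2, which acts on the product of SHMT2, was lower in the cells at -0.31 and higher in the population libraries at 0.15. The folate carrier SLC25A32 had 0.54 in the cells and -0.79 in the population libraries. MTHFD2L, a relative of MTHFD2, had 1.16 and 0.51. ALDH1L2, which oxidizes formyl folate, had 0.60 and -0.90, with 86.8% of its 12 h sum in 1 cell, and -0.28 without the highest cell of each group. Leaving out any 1 cell gave list medians between 0.11 and 0.66, and without the cells with a high mitochondrial share the median was 0.84 (percentile 98.7).

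Purine synthesis showed no shift of its list at 12 h: 3 of 12 enzymes were higher and 9 lower in the cells, with a median of -0.27 (percentile 32.1), against 0.010 in the population libraries (percentile 77.3). GART, which uses formyl folate in the pathway, was at 0.61 and ATIC, which uses it in a later step, at -0.51. Without the cells with a high mitochondrial share the purine median was 0.019. Polyamine synthesis had 4 of 6 members higher and 2 lower in the cells, and 3 higher and 3 lower in the population libraries. Its medians were 0.12 in the cells (percentile 89.6, and -0.011 to 0.17 when any 1 cell was left out) and 0.11 in the population libraries (percentile 85.4). AMD1, which makes the aminopropyl donor, was at 0.65 and 0.67, and ODC1, the entry enzyme, at 0.054 and -0.63. Polyamine catabolism and antizymes had medians of -0.16 (percentile 54.1) and 0.27 (percentile 95.4). The cytosolic folate enzymes had medians of -0.35 (percentile 25.2) and -0.51 (percentile 1.10), serine and glycine synthesis 0.039 (percentile 77.0) and -0.19 (percentile 25.2), and pyrimidine and deoxynucleotide synthesis -0.10 (percentile 65.9) and 0.11 (percentile 89.7), each in cells and then population.

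**Figure D3:**
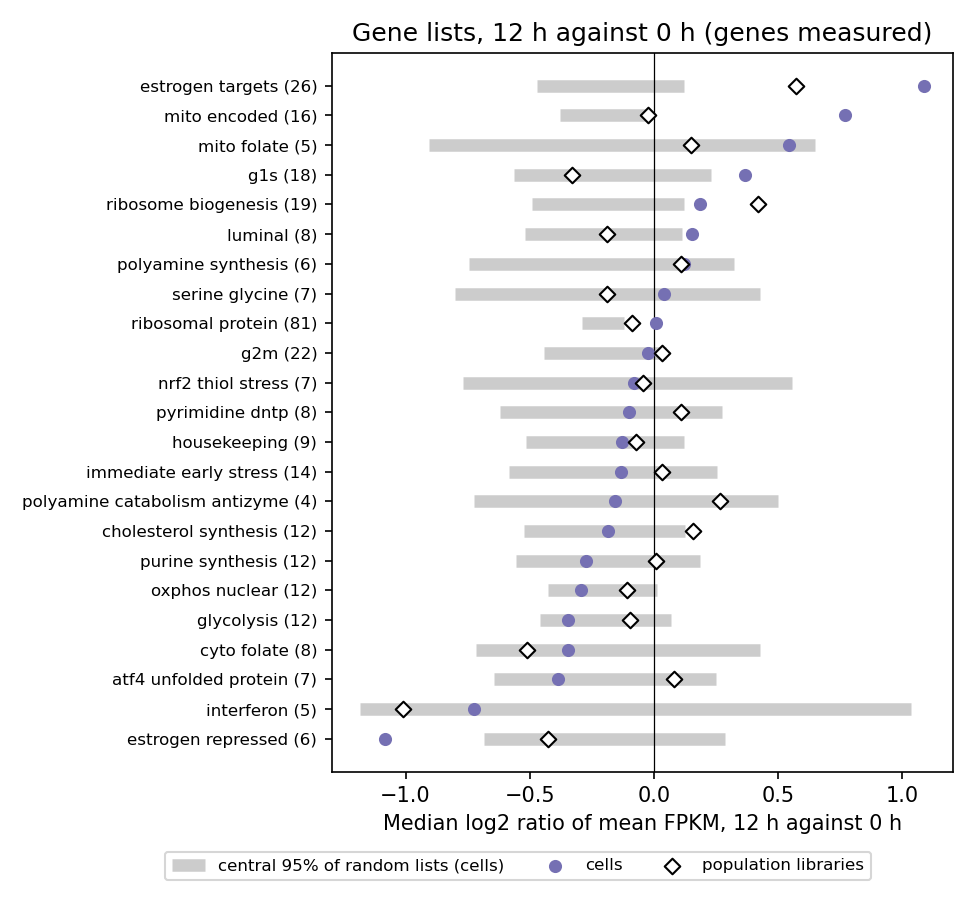
Median log2 ratio of mean FPKM at 12 h against 0 h on the x axis for each gene list on the y axis with at least 4 measured genes (their number in brackets), in cells (circles) and population libraries (diamonds), with the central 95% of random matched lists in the cells as gray bars. The estrogen targets lie at 1.09 in the cells and 0.57 in the population libraries, and the mitochondrial folate list at 0.54 lies inside its bar.

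Ribosome biogenesis factors as a list had medians above 0 at 12 h, 0.18 in the cells (percentile 99.0) and 0.42 in the population libraries. The members were mixed in the cells, with 11 higher and 8 lower of 19 and a median of 0.11 to 0.29 when any 1 cell was left out. In the population libraries 17 were higher and 2 lower, and 2 were at least 1.5-fold higher in both kinds of library. GNL3, a nucleolar GTPase, was lower at -0.74 and -0.048. FBL, which methylates ribosomal RNA, had 0.51 and 1.11, and NOP56, its partner, 0.59 and 0.42. Genes of the G1/S transition, which license and copy DNA, had a median of 0.37 in the cells (percentile 99.3) but -0.33 in the population libraries (percentile 1.68), and leaving out any 1 cell gave -0.085 to 0.65. PCNA, the sliding clamp of replication, was at 0.32 and -0.48, and MCM2, a subunit of the replicative helicase, at 1.85 and -0.20. The G2/M genes had -0.023 (percentile 92.0) and 0.031 (percentile 93.4). The mitochondrially encoded genes had 0.77 in the cells, -0.023 in the population libraries and -0.11 without the cells with a high mitochondrial share.

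Among the other lists at 12 h against 0 h, given as cells and then population, cholesterol synthesis had medians of -0.19 (percentile 55.2) and 0.16 (percentile 98.4), and glycolysis -0.35 (percentile 12.1) and -0.098. Nuclear genes of oxidative phosphorylation had -0.29 (percentile 21.9) and -0.11, the ATF4 and unfolded protein genes -0.39 (percentile 20) and 0.080, and the immediate early and stress genes -0.13 (percentile 58.7) and 0.033. Targets of NRF2, which respond to thiol stress, had -0.080 (percentile 62.5) and -0.046. Interferon-induced genes had -0.73 (percentile 22.4) and -1.01 (percentile 0.17), housekeeping genes -0.13 (percentile 68.2) and -0.073, and ribosomal protein genes 0.0093 (percentile 100) and -0.087. The luminal markers had 0.15 (percentile 98.5, but 95.5 without the cells with a high mitochondrial share) and -0.19 (percentile 31.4), and their keratins KRT8 and KRT18 reached 1 FPKM in all 24 cells at both times. Markers of other cell types were mostly rare: the fibroblast list had 2 measured members with a median of -0.43 (percentile 31.7), and the immune list 3 with -1.39 (percentile 3.78). Of the basal and myoepithelial markers, KRT5 and KRT14 were listed at 0 in all cells. ACTA2 reached 1 FPKM in 3 of 24 cells at 0 h, with a mean of 15.1 FPKM, and in 1 of 24 at 12 h, with a mean of 0.16; its mean at 3 h was 29.7, from 3 of 20 cells. The endothelial markers CDH5 and KDR were listed at 0 in all libraries.

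By the rule of size, the first 12 genes higher at 12 h than at 0 h in both kinds of library were 9 copies of the U1 small nuclear RNA, part of the spliceosome, and SGK3, KRT15 and CXCL12. SGK3, a kinase of the serum- and glucocorticoid-regulated family, averaged 12.8 ± 16.2 FPKM against 1.81 ± 4.57 (log2 ratio 2.30, population 2.02), and the keratin KRT15 47.2 ± 76.2 against 9.01 ± 18 (2.27, population 1.98). The U1 copies, which include RNU1-1, RNU1-2, RNU1-3, RNU1-4, RNU1-27P, RNU1-28P, RNVU1-7, RNVU1-9 and RNVU1-18, are near identical, and their reads cannot be assigned to single copies. Their log2 ratios of 2.37 to 2.76 in the cells rested on 1 cell, which held 73.5 to 81.2% of the 12 h sum, and were 0.60 to 0.85 without the highest cell of each group. Without the cells with a high mitochondrial share 7 of the 9 copies were lower at 12 h (RNU1-1 -0.24, RNVU1-18 -0.36), while the population ratios were 1.75 to 2.63. Counting U1 as 1 item, a choice made after its values were seen, also names STC2, EGLN2, HSPB8, CSNK1E, NPIPP1, LPIN1, LINC00173 and ANKRD18B. STC2, a secreted glycoprotein, had 1.57 in the cells and 3.07 in the population libraries, and the small heat shock protein HSPB8 1.84 and 1.44. For LPIN1, a phosphatidate phosphatase, 1 cell held 65.3% of the 12 h sum, and 1.34 became 0.81 without the highest cells; for NPIPP1, a member of a multicopy family, 1.34 became 0.82. Without the cells with a high mitochondrial share LPIN1 had 0.0025 and NPIPP1 0.29 in the cells, while their population ratios were 2.02 and 1.52. SGK3 and EGLN2 share exons with annotated read-through genes.

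The 12 genes named as lower at 12 h were REPS1, FBXO32, AC007000.11, AL358113.1, ISOC1, SELENBP1, KIAA1009, GHR, SLC16A4, BAMBI, ZNF561 and SOS1. FBXO32, a ubiquitin ligase component, averaged 6.47 ± 14.9 FPKM at 12 h and 24.3 ± 21.7 at 0 h (log2 ratio -1.76, population -1.75), and reached 1 FPKM in 37.5% and 91.7% of cells. BAMBI, a decoy receptor of the TGF-beta family, averaged 13.5 ± 21 against 47 ± 43.9 (-1.73, population -1.24). SELENBP1, a selenium-binding protein, had -1.41 in both kinds of library, and GHR, the growth hormone receptor, -1.33 and -1.28. SOS1, an exchange factor for RAS, had -1.20 and -1.78, but under 1 in size in 3 of 10 alternatives. REPS1, an endocytosis protein, ranked first at -2.72 and -2.06. For SLC16A4, of the monocarboxylate transporter family, 1 cell held 61.6% of the 12 h sum, and its ratio was -2.82 with it and -2.53 without the highest cells.

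The comparison of 3 h with 0 h asked what differed early. Of 24 measured estrogen targets, 19 were higher and 5 lower in the cells, with medians of 0.59 in the cells and 0.64 in the population libraries, both at percentile 100. MYC averaged 18.4 ± 38.8 FPKM at 3 h and 3.99 ± 14.9 at 0 h (log2 ratio 1.96, population 0.80). CXCL12 reached 1 FPKM in 6 of 20 cells (30%, 11.9 to 54.3%); its log2 ratio was 2.21, and 1.52 without the highest cell of each group. GREB1 and PGR had 0.61 and 0.40. The estrogen-repressed genes had 6 of 7 members lower in the cells, with a median of -0.25 (percentile 62.0, and -0.74 to -0.16 when any 1 cell was left out), but 4 of 7 higher in the population libraries, at 0.083 (percentile 77.4). Without the cells with a high mitochondrial share their median was -0.53 (percentile 4.25), still inside the random lists. Ribosome biogenesis factors had medians of 0.21 (percentile 99.7, and 0.092 to 0.31 when any 1 cell was left out) and 0.43 (percentile 99.9). The mitochondrially encoded genes had medians of 0.91 in the cells and 0.90 in the population libraries, and 0.25 without the cells with a high mitochondrial share. The pathways named in the title were not set apart at 3 h: the mitochondrial folate list had -0.11 (percentile 68.2), the purine list -0.45 (percentile 24.7) and the polyamine synthesis list -0.013 (percentile 84.3) in the cells.

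CYP1A1 and CYP1B1, which hydroxylate estradiol and are targets of the aryl hydrocarbon receptor, were higher at 3 h. CYP1A1 averaged 79.2 ± 118 FPKM in the cells against 14.3 ± 31.3 at 0 h, and 1183 against 107 in the population libraries. CYP1B1 averaged 140 ± 108 against 37.7 ± 33.8, and 61.7 against 20.3. SNHG1, a host gene of small nucleolar RNAs, had log2 ratios of 1.86 and 2.14. The rule also named U1 copies with 2.38 to 2.57 in the cells and 3.53 to 3.93 in the population libraries. The cell ratios were 1.93 to 2.16 without the highest cell of each group, but without the cells with a high mitochondrial share RNU1-1 had -0.012 and RNVU1-18 -0.21. It also named, with U1 as 1 item, ANKRD18B and SNX29. The lower genes were SMARCAL1, an annealing helicase, at -1.94, EPB41, a membrane skeleton protein, at -1.42, SMAD4, the common mediator of TGF-beta signaling, at -1.44, and the clone-named RP11-497H16.7, RP11-1103G16.1 and RP11-46C20.1. The G2/M list had 0.043 in the cells (percentile 99.5) and -0.42 in the population libraries (percentile 0.06), on opposite sides of the random lists. In the population libraries 22 of 22 members were lower. For the cells, leaving out any 1 cell gave -1.44 to 0.56. Without the cells with a high mitochondrial share the list lay inside the random lists (0.20, percentile 97.2). The G1/S list had 0.28 and 0.030, with -0.53 to 0.60 when any 1 cell was left out. Ribosomal protein genes had -0.19 in the cells (percentile 100) and -0.29 in the population libraries (percentile 2.025), on opposite sides of the random lists. Targets of NRF2 had 0.62 (percentile 98.7) and 0.063, but 0.12 (percentile 73.1) without the cells with a high mitochondrial share, and leaving out any 1 cell gave 0.011 to 0.68. The dye was the same at both times, but the well-name prefix differed, so what the prefix marks cannot be told apart from time.

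**Figure D4:**
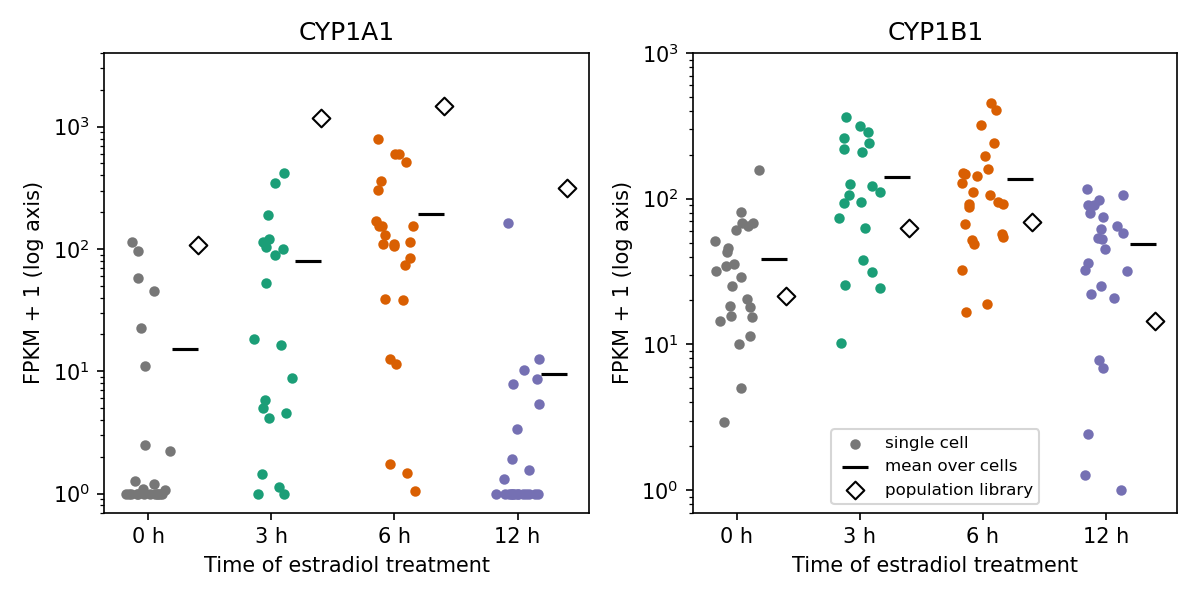
FPKM + 1 of CYP1A1 (left) and CYP1B1 (right) on a log axis, by time on the x axis, with each cell as a circle, the mean over cells as a bar and the population library as a diamond. The population library of CYP1A1 had 107, 1183, 1471 and 312 FPKM at 0, 3, 6 and 12 h.

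At 6 h against 0 h, the estrogen targets had 22 of 25 members higher and 3 lower in the cells, with medians of 0.90 (percentile 100) and 0.29 in the population libraries (percentile 99.8). GREB1 averaged 16.7 ± 16.5 FPKM against 6.48 ± 10.8 and reached 1 FPKM in 24 of 24 cells. The estrogen-repressed list had -0.60 (percentile 0.68) and -0.55 (percentile 3.65). Targets of NRF2 had 6 of 7 members higher in the cells, 4 of 7 in the population libraries and 3 in both. Their medians were 1.12 in the cells and 0.41 in the population libraries (percentile 98.0). SLC7A11, the cystine importer, had log2 ratios of 2.08 and 1.24, and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.72 and 1.34, while SRXN1, which repairs oxidized peroxiredoxins, had 1.12 in the cells and -0.35 in the population libraries. The immediate early and stress genes had 11 of 14 members higher in the cells and 12 of 14 in the population libraries, with medians of 0.59 and 0.82. FOS, a subunit of the AP-1 transcription factor, averaged 157 ± 144 FPKM against 81.5 ± 113, and HSPA1A, an inducible chaperone, 11.9 ± 11.5 against 3.30 ± 4.11.

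CYP1A1 was also the first gene by the rule at 6 h, with 192 ± 220 FPKM in the cells and 1471 in the population library, log2 ratios of 3.65 and 3.76. It was followed by CYP1B1-AS1, CTA-292E10.6, NECAB2, SGK3 and CYP1B1, of which CYP1B1 had 1.82 and 1.69. The libraries carry no strand, so reads of CYP1B1 and its antisense partner CYP1B1-AS1 cannot be separated. The lower genes were TMC6, HOMER1, SMAP2, RP11-14N7.2, KRT223P and RP11-138J23.1. HOMER1, a scaffold protein of synapses, had -1.55 and -1.57. For KRT223P, a keratin pseudogene, 1 cell held 95.7% of the 6 h sum, and its ratio was -1.59 with it and -3.22 without the highest cells. The G2/M genes had 19 of 22 members higher in the cells with a median of 0.73 (0.29 to 1.24 when any 1 cell was left out), and -0.19 in the population libraries. The mitochondrial folate list had 0.0027 (percentile 53.4), the purine list -0.20 (percentile 15.5) and the polyamine synthesis list 0.14 (percentile 80.5) in the cells, all inside the random lists. Ribosomal protein genes had 0.13 in the cells (percentile 100) and -0.55 in the population libraries (percentile 0.105), on opposite sides of the random lists. Dye and well-name prefix both differed between 6 h and 0 h.

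Between 6 h and 3 h, the estrogen targets were not set apart from other genes: 14 of 25 were higher and 11 lower in the cells, with a median of 0.12 (percentile 12.6), and the population median was -0.22 (percentile 5.22). GREB1 and PGR had log2 ratios of 0.63 and 0.30. The immediate early and stress genes had medians of 0.78 (percentile 99.3) and 0.29 (percentile 99.5), with FOS at 0.96 and 0.84. Targets of NRF2 had 0.91 (percentile 98.5) and 0.014, with GCLM at 0.91 and 1.28; without the cells with a high mitochondrial share the list had 0.45 (percentile 94.1), inside the random lists. The G2/M genes had 20 of 22 members higher in the cells and 19 of 22 in the population libraries, with medians of 0.59 (percentile 99.5) and 0.36. The G1/S genes had -0.12 (percentile 2.17) and -0.14. Leaving out any 1 cell gave 0.15 to 2.21 for G2/M and -0.46 to 0.60 for G1/S. Housekeeping genes had 0.61 (percentile 97.6) and -0.17, and 0.23 (percentile 96.5) without those cells. TOP2A, a topoisomerase of dividing cells, had 0.79, or 1.60 without the highest cell of each group. The mitochondrially encoded genes had -0.94 in the cells, -1.03 in the population libraries and -0.30 without the cells with a high mitochondrial share.

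The genes named as higher at 6 h than at 3 h were entries without a known function: the clone-named RP11-707G14.1, RP11-1103G16.1, RP11-467L13.4, RP11-465L10.7 and RP11-139K1.2, and RN7SL99P, a pseudogene of the 7SL RNA. Those named as lower included the small nuclear RNA RN7SK, which binds an elongation factor, at -1.94 and -1.60, and its pseudogene RN7SKP71, which can share its reads. At 12 h against 0 h RN7SK had 1.15 and RN7SKP71 1.11 in the cells, but -0.14 and -0.049 without the cells with a high mitochondrial share. Such cells occurred at 3 h but not at 6 h, so the cell ratios of these 2 genes may depend on them. GAMT, which makes creatine, had -1.71 and -1.89, and MKNK2, a kinase of translation initiation, -2.00 and -1.57. RP11-464F9.20 had -1.87 and -1.59. For RNU6-37P, a U6 pseudogene, 1 cell held 79.2% of the 3 h sum, and -2.79 became -0.83 without the highest cells. The 2 times shared the well-name prefix but not the dye.

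Across genes with a mean of at least 1 FPKM, the log2 ratios of cells and population libraries were weakly related, with Pearson's r of 0.058 for 12 h against 0 h, 0.10 for 3 h against 0 h, 0.065 for 6 h against 0 h and 0.042 for 6 h against 3 h. The 2 kinds of ratio had the same sign for 49.8%, 50.55%, 48.3% and 44.6% of these genes, in the same order. A gene with a ratio of 0 in only 1 kind of library counted as differing in sign, which lowers these shares, so 50% is not their chance level. Across genes with a mean of at least 10 FPKM they were 55.8%, 57.9%, 51.8% and 45.6%. The rule for named genes selects those that agree in both kinds of library, so their agreement is not support for them. Genes are not independent replicates, and no p-value is given. Relative to 0 h, the median log2 ratio of all such genes in the cells was -0.17 at 12 h, -0.30 at 3 h and -0.026 at 6 h, and it was 0.27 for 6 h against 3 h.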

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

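Settings that touch mitochondrial genes or single cells were chosen after seeing the data; the others were fixed before. No paired analysis was possible because 1 culture per time point was assumed and numbers only name cells. Across alternatives, 868 list medians stayed the same, 284 moved, 45 became weaker, 34 stronger and 25 reversed; of the gene ratios 1067 stayed the same, 106 became weaker, 44 stronger, 15 moved and 18 reversed. Shares of cells stayed the same in 37 cases and moved in 22, and correlations stayed in 7 and moved in 1. A list median counted as reversed only if it lay outside the random lists as reported and changed sign. It was weaker if it came to lie inside them and stronger if it came to lie outside. It moved if it shifted by more than 1 SD of their medians. A gene ratio counted as reversed only if it was at least 1 in size as reported. Other changes of sign are not among the reversed. The estrogen target list at 12 h against 0 h lay at percentile 100 under all 13 alternatives (0.62 to 1.29). At 3 h against 0 h it had 0.41 to 0.97 and at 6 h against 0 h 0.33 to 0.98, outside the random lists in 13 of 13 each. The polyamine synthesis list stayed inside them at 12 h, with -0.022 to 0.34. Some of the 13 alternatives could not change where a list lay. Centering shifts a list and its random lists alike. Leaving out cells with few genes removed no cell at 0, 6 or 12 h, and leaving out high-share cells removed none at 0 h and 6 h. Medians in population libraries below use the members that pass the filter there, so they differ from the medians of the members measured in cells. The causes of the shifts below were not tested. Absolute depth is unknown, and low genes in single cells are limited by it.

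The estrogen target list at 12 h against 0 h was 0.71 with a pseudocount of 5, 0.89 without a filter, 0.92 with means of log values, 1.26 when centered, 0.62 in population libraries, 1.29 without mitochondrial genes and 1.27 without those genes and the high-share cells. At 3 h against 0 h it was 0.41 with a pseudocount of 5, 0.78 with a filter at 5, 0.89 centered, 0.87 without high-share cells, 0.96 without mitochondrial genes and 0.97 with both. At 6 h against 0 h it was 0.63 with a pseudocount of 5, 0.70 without a filter, 0.74 with means of log values and 0.33 in population libraries. For 6 h against 3 h it was 0.38 with means of log values, 0.30 with trimmed means, 0.29 rescaled, -0.16 centered, -0.23 in population libraries, -0.096 without high-share cells, -0.16 without mitochondrial genes and -0.12 with both.

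At 12 h against 0 h the mitochondrial folate list was -0.19 with means of log values, -0.32 in population libraries, 0.73 rescaled, 0.84 without high-share cells and 1.09 with both mitochondrial changes; the last 3 lay outside the random lists. The purine list was 0.058 in population libraries, 0.019 without high-share cells and 0.0076 with both. With means of log values the luminal list was -0.030 and the ribosomal protein list -0.16. Rescaled, the ribosomal protein list was -0.025. In population libraries the G1/S list was -0.36, the luminal list -0.19, the mitochondrially encoded list -0.038 and the ribosomal protein list -0.087; without high-share cells the mitochondrially encoded list was -0.11. MCM2 was -0.20 and PDZK1 0.27 in population libraries. Of the genes named as lower, SOS1 (to -0.75) and KIAA1009 (to -0.73) were under 1 in size in 3 of 10 alternatives, GHR (to -0.96) in 2 and ISOC1 (to -0.75) in 1.

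At 3 h against 0 h the NRF2 list was -0.33 with a filter at 5 and -0.011 with trimmed means. The G1/S list was -0.58 with means of log values and -0.54 trimmed. The G2/M list was -0.50 with means of log values, -1.39 trimmed, -0.064 rescaled and -0.42 in population libraries. The ribosomal protein list was 0.11 centered, 0.15 without high-share cells and 0.17 with both. At 6 h against 0 h in population libraries the G2/M list was -0.19, the ribosomal protein list -0.55 and SRXN1 -0.35. For 6 h against 3 h the G1/S list was 0.25 with means of log values, 0.75 trimmed and 0.042 rescaled, and the housekeeping list was -0.17 in population libraries.

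Among U1 copies at 12 h against 0 h, trimmed means gave -0.0010 for RNU1-1, -0.020 for RNU1-2, -0.032 for RNU1-3, -0.0055 for RNU1-4, -0.13 for RNVU1-18 and -0.074 for RNVU1-7. Without high-share cells these were -0.24, -0.25, -0.19, -0.17, -0.36 and -0.32, and RNVU1-9 was -0.19. At 3 h against 0 h without high-share cells RNU1-1 was -0.012 and RNVU1-18 -0.21.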

Other observations

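All tests in this part were chosen after the results were seen.

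Immediate early and stress genes were higher in the cells than in the population library of the same time, with a median log2 ratio of 1.68 at 0 h, 1.37 at 3 h, 1.54 at 6 h and 1.61 at 12 h. FOS averaged 81.5 FPKM in the 0 h cells and had 2.19 in the population library. Per cell, the mean log2(FPKM + 1) over the 14 genes of this list was above the 0 h median in 24 of 24 cells at 6 h. The luminal markers were also higher in the cells, at 0.86, 0.38, 1.05 and 1.10, and the mitochondrially encoded genes at 1.09, 1.13, 0.92 and 1.90. Ribosomal protein genes had -1.01 at 0 h, which lay inside the random lists (percentile 5.59).

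Proliferation genes differed strongly between cells of the same time. The mean log2(FPKM + 1) over 22 G2/M genes was 2.14 ± 2.07 at 0 h, 1.66 ± 2.06 at 3 h, 2.5 ± 2.71 at 6 h and 2.49 ± 2.14 at 12 h, with a range of 0.51 to 7.41 at 0 h. TOP2A reached 1 FPKM in 8 of 24 cells at 0 h (33.3%, exact 95% interval 15.6 to 55.3%) and in 14 of 24 at 12 h (58.3%, 36.6 to 77.9%).

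The higher level of the estrogen targets may be a response to estradiol, as a hypothesis. By design, 3 h and 0 h share the dye, and 12 h and 0 h share the prefix. In the cells, the ratio of 12 h to 0 h exceeded that of 6 h to 3 h, with the same change of dye, by a median of 0.77 (random lists up to 0.0069). This argues against the dye as the sole cause at 12 h, unless a fall from 3 h to 6 h offset a dye effect. Such a fall is not excluded: 6 h against 3 h gave 0.12 in the cells, -0.096 without the high-share cells and -0.22 in the population libraries, all inside the random lists. The high-share cells are argued against by a list median of 1.21 without them at 12 h. The prefix stays open for 3 h and 6 h, where 6 h had 0.90, since prefix and time cannot be told apart. A 0 h culture that stood apart also stays open: 12 h against 3 h gave 0.34, inside the random lists, which reached 0.41, and the population libraries gave 0.15, with random lists up to 0.17.

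CYP1A1 and CYP1B1 were higher at 3 and 6 h. The high-share cells are argued against, since the smaller of the 2 log2 ratios at 3 h was 2.24 without them. The dye, the same at 3 h and 0 h, stays open at 6 h for CYP1A1, as does the prefix at both times for both genes. CYP1A1 in the population libraries had 1.53 at 12 h against 0 h, with the same change of dye and no change of prefix. In the cells it had -0.69, with 78.5% of the 12 h sum in 1 cell and -1.93 without the highest cells. CYP1B1 had 0.35 in the cells and -0.55 in the population libraries at 12 h against 0 h. Between 6 h and 3 h, with the same change of dye, it averaged 136 against 140 FPKM in the cells. Its population libraries had 68.0 against 61.7. For this gene both comparisons speak against a dye effect of the size seen at 6 h, unless a change with time offset it. CYP1A1 was higher at 6 h than at 3 h, at 192 against 79.2 FPKM in the cells and 1471 against 1183 in the population libraries. A response to estradiol or to a ligand of the aryl hydrocarbon receptor was not tested.

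Cells with a high mitochondrial share occurred at 3 and 12 h. Their median relative depth was lower than that of the other cells of their time, 0.863 against 1.03 at 3 h and 0.918 against 1.03 at 12 h. Their shares exceeded those expected from their depth, by a line through the cells of 0 h and 6 h, by at least 31.1 percentage points (residual SD 8.09). This excess cannot decide on shallower sequencing as the cause. The cells were picked for shares of at least 50%, and all cells of 0 h and 6 h lay below that. Cells of 0 h and 6 h did reach relative depths as low as 0.606 without such shares. As to a smaller rise in the other cells at 12 h, their median share was 23.4%, against 24.1% at 0 h. Without the high-share cells the mitochondrially encoded list at 12 h had -0.11, and the population libraries had -0.023. The values of the other cells cannot decide on such a rise. These cells were kept for shares under 50%, which removed 6 of 24 cells at 12 h and 0 of 24 at 0 h and so lowered the 12 h values. Over all cells of 12 h the median share was 26.3%. At 3 h a smaller rise also stays open, with a median share of 29.3% in the other cells and a list median of 0.25. Loss of cytoplasmic RNA from damaged cells was not tested, and no biological explanation was tested.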
